A study of Homo sapiens with 16 samples.

How the data were processed

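Poly-A mRNA and small RNA were measured in 16 human libraries, 8 of each kind, made from the same total RNA preparations of left and right atrial tissue of 4 patients. Per the labels' protocols, total RNA came from atrial tissue with a miRNeasy kit, and small RNA libraries were size-selected and read as short single-end reads. The deposited values are raw read counts without normalization. Per the deposited description of the count tables, small RNA reads were aligned with Bowtie to the hairpins of miRBase release 17 with 1 mismatch allowed, and hairpins that share a mature sequence were collapsed. By the same description, mRNA reads were aligned with TopHat and tabulated against RefSeq genes. The submitters' processing notes also name CASAVA 1.3 and the human build hg19. The versions of TopHat and Bowtie, the counting tool and the use of strand are not given in the sources used here. Genes that overlap, sit antisense to each other or share reads with a near-identical copy are therefore uncertain, and so are miRNA copies, since the collapse can move reads between them. No genome of that build was used, so no coordinates are given.

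The mRNA tables hold 23191 named rows, with 518 symbols on more than 1 row. The row with the largest total was kept for each. To protect the donors, 102 symbols (XIST, TSIX and genes on the Y chromosome) were left out of all tables, which left 22154 genes. The miRNA tables hold 939 rows. The first line of the mRNA tables names no gene and holds a count of 0. Gene names are those of the deposited tables.

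Groups and patient numbers came from the sample titles, and the series' design text says that left and right atria were matched within patients. The main test was edgeR 4.0.16 (R 4.3.3) with TMM factors, filterByExpr with its defaults (a count minimum of 10), and quasi-likelihood fits with patient as a block, which leaves 3 residual degrees of freedom. P-values were adjusted by the Benjamini-Hochberg method over 15127 genes or 385 miRNAs, with a threshold of 0.05, and all were two-sided. Fold changes are labelled left over labelled right, with standard errors from the fit. Gene lists were tested with camera in limma 3.58.1 on log2 CPM with a prior count of 2, the block and a preset correlation of 0.01, over the 28 mRNA lists with at least 5 tested genes and the 9 miRNA lists with at least 3. Alongside stood camera with an estimated correlation, fry, and counts adjusted over the list alone. In the miRNA lists each hairpin copy of a name counted as a separate member, and the lists were not run with copies added together. miRNA and host gene correlations used 1e+05 permutations. The tests, the lists and the alternatives were fixed before the data were examined, apart from 3 alternatives and all tests of explanations, which were chosen after seeing the data.

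Named genes followed a rule fixed at the same time. It took BMP10, NPPA and NPPB always, and the 10 genes or 8 miRNAs with the largest change in each direction among those past the threshold with the same sign in 4 of 4 pairs, of which there were 0. It also took up to 4 genes or 3 miRNAs with the smallest p from each list, those with p over 0.05 only as examples of no call. A further gene that the rule takes is not reported here. Outside the rule, the most abundant features and pairs of miRNA and host gene are named as well. Other names outside the rule are said to be so where they appear.

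The pairing was checked by the correlation, across genes, of the deviations from the labelled side means between libraries with the same patient number. For patients 1 to 4 it was -0.14, 0.54, -0.37 and 0.06 in mRNA and -0.14, 0.43, -0.22 and 0.08 in miRNA. The block was kept because the design text states the pairing. A check of donor identity found that 2 of 4 labelled pairs did not match. BMP10 and HAMP, described in the report, also contradict some labels, so samples were analysed as labelled and no library was regrouped.

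Alternatives were DESeq2 1.42.0, limma voom, other size factors, filters and thresholds, no block, and leaving out each patient or the most abundant features. Depth limits low counts most. A count of 0 allows up to 3 counts, and such limits cover counting error only. Counts were simulated with means fitted to the real counts by patient number without side, and with the estimated dispersions. On these the mRNA test recovered 12% of 50 genes changed 2-fold, 74% of 50 changed 4-fold, 90% of 50 changed 8-fold and 100% of 50 changed 16-fold among 15127 genes, with 12 false calls. The miRNA test recovered 20% of 10 miRNAs changed 2-fold and 100% of 10 changed 4-fold among 385, with 0 false calls. The simulated features were independent, and every side label and patient number was right. These shares therefore do not give the power to find differences between atria under labels that are in doubt. On simulated independent genes camera called the list that was shifted 2-fold and 0 of the 26 mRNA lists and 0 of the 7 miRNA lists that shared no member with it.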

Results

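Total RNA from pieces labelled as human left and right atrium, in pairs labelled by patient, was sequenced as poly-A mRNA libraries and as small RNA libraries made from the same RNA preparations. The atria are the thin-walled upper chambers of the heart, and the design asks which mRNAs and miRNAs differ between the left and the right atrium of the same patient. Each assay had 8 libraries, 4 labelled left and 4 labelled right, from 4 numbered patients. Total mRNA counts ran from 10832397 to 18682350 in the libraries labelled left and from 12900412 to 19567339 in those labelled right. Total miRNA counts ran from 7553225 to 14470335 and from 7473914 to 16486226.

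The mRNA libraries were rich in atrial muscle transcripts. NPPA, which encodes atrial natriuretic peptide, took 4.64% ± 0.456 (SD, n = 4) of the counts in the libraries labelled left and 5.07% ± 3.15 (SD, n = 4) in those labelled right. MYH6, the main atrial myosin heavy chain, took 3.54% ± 0.958 and 3.56% ± 0.517 (SD, n = 4 each). MYH7, the slow myosin heavy chain that dominates the ventricle, took 1.97% ± 0.878 and 1.45% ± 0.284. In the small RNA libraries hsa-mir-143, a miRNA of smooth muscle and mesenchymal cells, took 30.4% ± 5.17 and 30.1% ± 3.67 of the counts (SD, n = 4 each). The muscle miRNAs hsa-mir-378 and hsa-mir-1-1 followed, at 7.34% ± 1.17 and 5.88% ± 1.23 in the libraries labelled left (SD, n = 4).

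BMP10, a growth factor made in the right atrium, did not follow the side labels. It had 14700 and 24273 counts in the libraries labelled right of patients 1 and 2, but 25 and 14 in those labelled right of patients 3 and 4. Among the libraries labelled left it had 62 counts for patient 1 and 37 for patient 4, against 42376 for patient 2 and 1072 for patient 3. HAMP, which encodes the iron hormone hepcidin and was looked at after the values were seen, split the libraries as BMP10 did. HAMP counts were 2071, 4027, 975 and 1739 in the libraries labelled right of patients 1 and 2 and labelled left of patients 2 and 3, and between 4 and 24 in the others. In edgeR's quasi-likelihood test the labelled sides differed by a log2 fold change of 0.80 ± 1.93 (SE) for BMP10, with a mean of 552 ± 1049 CPM (counts scaled to the library size) in the libraries labelled left and 549.7 ± 636 CPM in those labelled right (SD, n = 4 each). The adjusted p in that edgeR test was 0.9998, and the sign turned without the patient block (-0.04), in limma voom (-1.34) and without patient 3 (-0.85). Because these values contradict some labels, and 2 of the 4 labelled pairs failed a check of donor identity, every direction in the text is between libraries labelled left and libraries labelled right, not between atria.

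**Figure D1:**
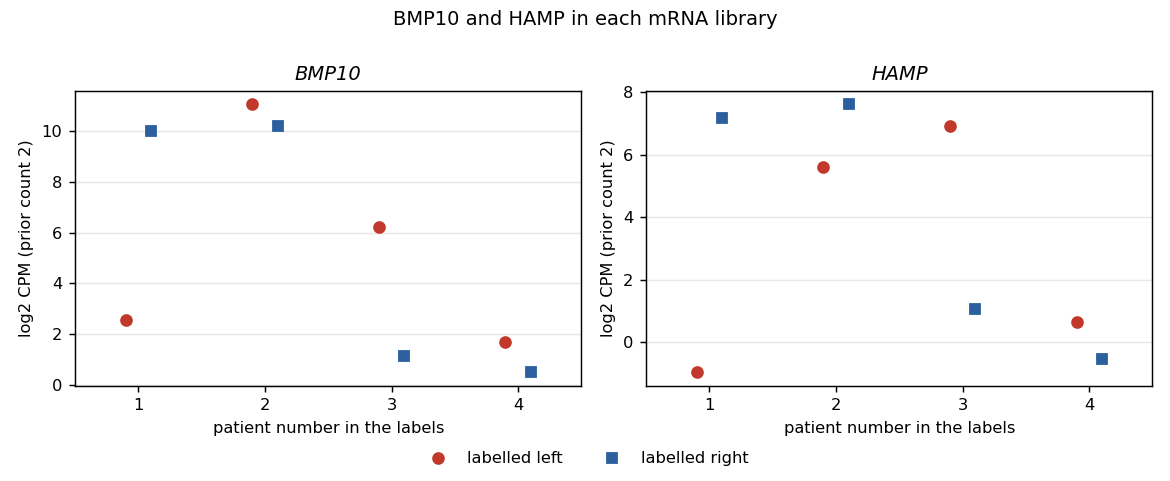
Expression of BMP10 and HAMP as log2 CPM with a prior count of 2 (vertical axis) against the patient number in the labels (horizontal axis), with 1 point per mRNA library, circles for libraries labelled left and squares for those labelled right. Both genes were low in the libraries labelled left of patients 1 and 4 and labelled right of patients 3 and 4, and higher in the other 4.

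No gene was called by edgeR between the 4 libraries labelled left and the 4 labelled right. With patient as a block, edgeR's quasi-likelihood test called 0 of 15127 genes higher and 0 lower at an adjusted p of 0.05, with a smallest adjusted p of 0.9998. At an unadjusted p under 0.05 there were 326 genes, where chance alone gives 756.4. DESeq2 called 1 gene higher and 3 lower, and limma voom called 0. The 1 gene higher by DESeq2 was CEBPA, a transcription factor of fat and myeloid cells, with a log2 fold change of 2.12 ± 0.35 (SE; DESeq2 adjusted p = 1.18e-05). The 3 lower were ASTN2, a neuronal adhesion protein, at -2.30 ± 0.44 (SE), LOC388588 at -1.69 ± 0.34 and TUBB4, a beta-tubulin, at -1.49 ± 0.30. These 4 genes went 1 way in 4 of 4 labelled pairs, and they were named after their values were seen. A test with patient as a block favours such genes, so their shared sign is no separate support. Over all tested genes, 1261 (8.34%) had the same sign in 4 of 4 pairs, against 12.5% by chance. NPPA had a log2 fold change of -0.04 ± 0.43 (SE) and NPPB, the second natriuretic peptide, 0.18 ± 0.69. Their direction turned with the patients kept, from -0.34 without patient 1 to 0.35 without patient 4 for NPPA and from -0.32 without patient 2 to 0.94 without patient 3 for NPPB.

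Genes of oxidative phosphorylation, glycolysis, the sarcomere and smooth muscle lay lower, as groups, in the libraries labelled left by camera with a preset correlation between genes of 0.01, and no call held with an estimated correlation or with fry. Of 44 genes of oxidative phosphorylation 41 had a negative log2 fold change (median -0.31; camera adjusted p = 8.04e-08, against an adjusted p of 0.771 with an estimated correlation), led by ATP5G1, a subunit of ATP synthase, at -0.90 ± 0.20 (SE). Of 22 glycolysis genes 20 were negative (median -0.25; camera adjusted p = 0.00364, against an adjusted p of 0.674 with an estimated correlation), while PFKFB3, which makes the activator of phosphofructokinase, stood at 0.72 ± 0.26 (SE). Of 31 sarcomere genes 21 were negative (median -0.19; camera adjusted p = 0.00394, against an adjusted p of 0.785 with an estimated correlation), among them MYL3, a myosin light chain of ventricle and slow muscle, at -1.66 ± 0.70 (SE) and the atrial MYBPHL at -0.59 ± 0.20. Of 16 smooth muscle and pericyte genes 13 were negative (median -0.24; camera adjusted p = 0.0398, against an adjusted p of 0.829 with an estimated correlation), among them the contractile genes TAGLN at -1.68 ± 0.58 (SE) and ACTA2 at -1.04 ± 0.32. By library, the mean of the oxidative phosphorylation genes, as log2 CPM centred per gene, was 0.61 and 0.49 in those labelled right of patients 4 and 3, and -0.51 to 0.10 in the other 6. That of the sarcomere genes was 0.66 in the library labelled right of patient 3 and -0.49 to 0.23 in the other 7, and MYL2, the ventricular myosin light chain, named after its values were seen, stood there at 1343 CPM, against 3.31 to 148. TAGLN averaged 272 ± 84.5 CPM in the libraries labelled left and 967 ± 572 CPM in those labelled right (SD, n = 4 each). In each of the 4 lists 0 members passed edgeR's threshold, over all genes or adjusted over the list alone, and 6 list entries had an unadjusted p under 0.05. Leaving out patient 3 gave a preset camera adjusted p of 0.673 for sarcomere, 0.998 for smooth muscle and 0.0712 for glycolysis. Leaving out patient 2 gave 0.0762 for glycolysis, and leaving out patient 4 gave 0.0551 for smooth muscle. MYL3 ran from -1.06 without patient 2 to -2.39 without patient 4.

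Genes of red cells, lymphocytes and mast cells, adipocytes, lymphatic endothelium and fatty acid oxidation lay higher, as groups, in the libraries labelled left by the same test, and again no call held with an estimated correlation or with fry. All 5 tested red cell genes were positive (median log2 fold change 2.50; camera adjusted p = 0.000318, against an adjusted p of 0.674 with an estimated correlation), with HBB, beta-globin, at 2.70 ± 1.33 (SE). Of 16 genes of lymphocytes and mast cells 15 were positive, with a median of 0.85 (camera adjusted p = 1.31e-07, against an adjusted p of 0.674 with an estimated correlation). Among them were the mast cell genes CPA3 at 1.32 ± 0.42 (SE) and HDC at 1.72 ± 0.62, and the leukocyte antigen PTPRC at 1.14 ± 0.47. Counts were low for CPA3, at 2 to 47, and HDC, at 0 to 34. Of 16 adipocyte genes 15 were positive (median 0.76; camera adjusted p = 1.65e-06, against an adjusted p of 0.674 with an estimated correlation), among them PLIN1, a coat protein of lipid droplets, at 2.76 ± 1.14 (SE) and CIDEA at 1.50 ± 0.61. PLIN1 averaged 75.3 ± 107 CPM in the libraries labelled left and 8.60 ± 11.8 CPM in those labelled right (SD, n = 4 each). By library, the mean of the red cell genes, centred as above, was -3.59 and -2.81 in those labelled right of patients 2 and 3 and 0.55 to 1.51 in the other 6. That of lymphocytes and mast cells was -1.11 and -1.67 in the same 2 and 0.27 to 0.69 in the other 6, highest in the library labelled right of patient 4. That of adipocytes was 2.73 and 0.98 in the libraries labelled left of patients 1 and 2 and lowest, at -1.55, in that labelled left of patient 3. All 8 genes of lymphatic endothelium were positive (median 0.41; camera adjusted p = 0.00636, against an adjusted p of 0.674 with an estimated correlation), with RELN at 1.58 ± 0.75 (SE), and by library their mean was -1.23 in that labelled right of patient 3 and -0.26 to 0.48 in the other 7. Of 30 genes of fatty acid oxidation 19 were positive (median 0.08; camera adjusted p = 0.0497, against an adjusted p of 0.990 with an estimated correlation), led by ANGPTL4, a secreted inhibitor of lipoprotein lipase, at 1.23 ± 0.30 (SE). In these 5 lists 0 members passed edgeR's threshold, over all genes or adjusted over the list alone. Leaving out patient 3 gave a preset camera adjusted p of 0.0735 for red cells, 0.0685 for lymphocytes and mast cells and 0.0731 for lymphatic endothelium, and leaving out patient 1 gave 0.0557 for adipocytes. Fatty acid oxidation stood at 0.199 and 0.0551 without patient 2 or 4 and turned lower, at 0.812, without patient 1, and lymphatic endothelium at 0.0579 without patient 4. Over the left-out patients the log2 fold change ran from 1.53 to 4.18 for HBB, 1.71 to 3.87 for PLIN1, 0.93 to 2.12 for CIDEA, 0.75 to 1.50 for PTPRC and 0.89 to 2.40 for RELN.

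**Figure D2:**
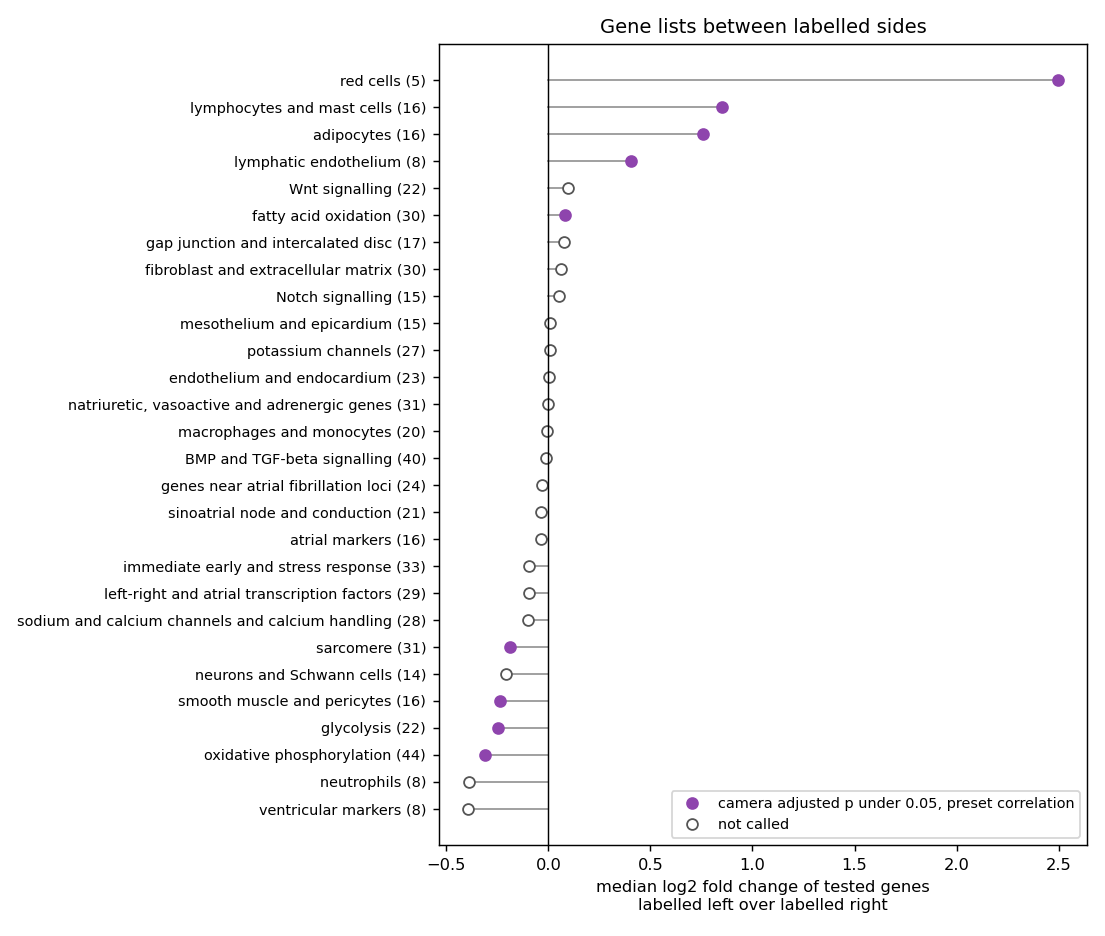
Median log2 fold change of the tested genes of each mRNA list, labelled left over labelled right (horizontal axis), with 1 row per list and the number of tested genes in brackets. Filled points mark the 9 lists with a camera adjusted p under 0.05 at the preset correlation, from -0.31 for oxidative phosphorylation to 2.50 for red cells, and open points mark the other lists. With an estimated correlation 0 lists passed.

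The remaining 19 mRNA lists were not called. Left-right and atrial transcription factors had a median log2 fold change of -0.09 (camera adjusted p = 0.743), with TBX3, a regulator of the conduction system, at -1.07 ± 0.37 (SE). Genes of the sinoatrial node and conduction stood at -0.03 (0.816 by the same test), with the axonal adhesion gene CNTN2 at -1.70 ± 0.47 (SE) and lower in 4 of 4 labelled pairs. CNTN2 counts were low, at 2 to 25 in the libraries labelled left and 5 to 102 in those labelled right. By library, the mean of that list, as log2 CPM centred per gene, followed BMP10 and not the labels, at 0.24 to 0.61 in the libraries labelled right of patients 1 and 2 and labelled left of patients 2 and 3, and at -0.53 to -0.40 in the other 4. Sodium and calcium channels and calcium handling stood at -0.10 (0.264), with the channel subunit SCN3B at -0.97 ± 0.37 and the atrial calcium pump regulator SLN at -0.62 ± 0.26. Potassium channels had a median of 0.01 (0.999), gap junction and intercalated disc genes 0.08 (0.527), atrial markers -0.04 (0.476) and ventricular markers -0.39 (0.200). Genes near atrial fibrillation loci had a median of -0.03 (0.950), and natriuretic, vasoactive and adrenergic genes 0.00 (0.816). In the latter list AGTR1, the angiotensin II receptor, stood at 1.09 ± 0.24 (SE) and was higher in 4 of 4 labelled pairs, at 14.5 ± 2.68 against 6.99 ± 2.43 CPM (SD, n = 4 each). Its values did not overlap, at 10.5 to 15.99 CPM in the libraries labelled left and 4.03 to 9.97 CPM in those labelled right, with an adjusted p of 0.9998 in edgeR's test. AGTR1 was named for its small p, which favours such a gap, and the share of all genes with 1 was not counted.

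Signalling lists had medians near 0 between the labelled sides. The median was -0.01 for BMP and TGF-beta signalling (camera adjusted p = 0.999), 0.10 for Wnt signalling (0.819) and 0.05 for Notch signalling (0.950). By library the mean of the BMP and TGF-beta list was 0.21 to 0.44 in the 4 libraries high in BMP10 and -0.38 to -0.33 in the other 4. BMP10 and HAMP, which mark that split, are members of this list and add to the difference. The mean of the Wnt list was 0.14 to 0.33 and -0.27 to -0.15 in the same libraries, so the labelled sides mix libraries that differ. Members of the signalling lists with the smallest p were the BMP inhibitor CHRDL1 at 0.94 ± 0.28 (SE) and BMP5 at 1.33 ± 0.49, both higher in 4 of 4 labelled pairs, WNT6 at -1.41 ± 0.55, and the Notch target HEYL at -0.54 ± 0.22. Counts were low for BMP5, at 3 to 33, and WNT6, at 3 to 49. Immediate early and stress genes had a median of -0.09 (0.457), with the metallothionein MT2A at -1.20 ± 0.48 (SE). Among other cell types, fibroblast and extracellular matrix genes stood at 0.06 (0.630), with elastin, ELN, at -0.91 ± 0.25 (SE) and the proteoglycan LUM at 1.01 ± 0.33. Endothelium and endocardium stood at 0.00 (0.912), mesothelium and epicardium at 0.01 (0.527) and macrophages and monocytes at -0.01 (0.705). Neutrophil genes stood at -0.39 (0.816) and genes of neurons and Schwann cells at -0.21 (0.212), with the neurotrophin receptor NGFR at -0.67 ± 0.22 (SE) and SNAP25 at 1.42 ± 0.52. Of the HOX genes 4 were tested, too few for camera, and their median was -0.23. The median and the mean or camera direction had opposite signs for left-right factors, potassium channels, BMP and TGF-beta signalling, endothelium, mesothelium and macrophages, each with a median within 0.10 of 0. Several mesothelial genes were high in both libraries of a labelled pair, with ITLN1, which encodes the lectin omentin, at 2098 CPM in the library labelled left of patient 4 and 1208 CPM in that labelled right, against at most 127.5 CPM in the other 6 libraries. MSLN, the mesothelial surface protein mesothelin, stood at 144 and 141 CPM in that pair and at most 13.02 CPM elsewhere. ITLN1 and MSLN are outside the rule and were named after their values were seen. Over all lists 28 of 557 distinct tested members had an unadjusted p under 0.05 and 0 passed when adjusted over the list alone.

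**Figure D3:**
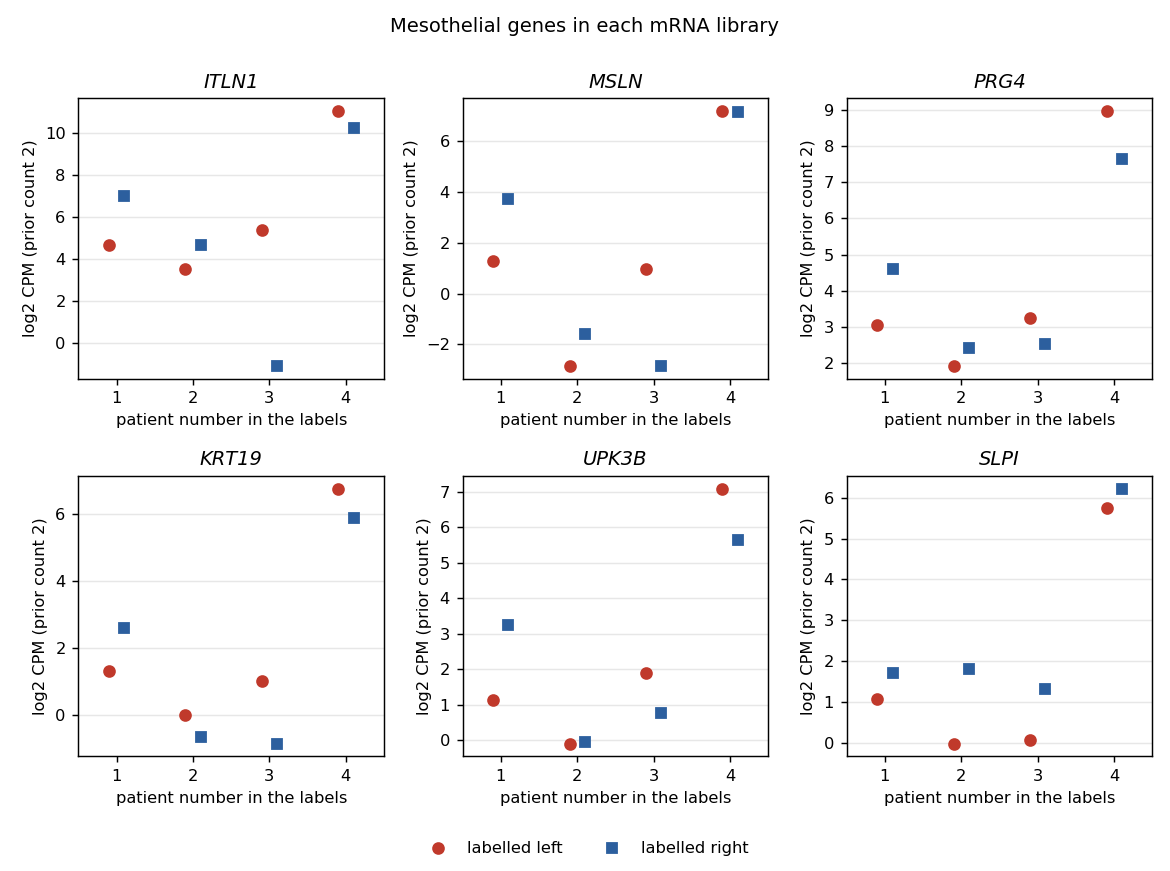
Expression of 6 mesothelial genes as log2 CPM with a prior count of 2 (vertical axis) against the patient number in the labels (horizontal axis), with 1 point per mRNA library, circles for libraries labelled left and squares for those labelled right. Both libraries labelled patient 4 lie above the other 6 libraries for each of the 6 genes. These are the genes with the largest such difference among the 15 tested of the list. The pair held the 2 highest libraries for 10 of the 15.

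No miRNA was called by edgeR between the labelled sides either. With patient as a block, edgeR's quasi-likelihood test called 0 of 385 miRNAs higher and 0 lower, with a smallest adjusted p of 0.683, and 17 had an unadjusted p under 0.05 where chance gives 19.2. limma voom called 0, and DESeq2 called 2 higher and 1 lower. The 2 higher by DESeq2 were hsa-mir-216a and hsa-mir-217, neighbours in a single cluster known from pancreas and endothelium. Their log2 fold changes were 2.16 ± 0.42 (SE; DESeq2 adjusted p = 0.000123) and 1.77 ± 0.39 (SE; DESeq2 adjusted p = 0.00127). In CPM hsa-mir-216a averaged 34.9 ± 34.1 in the libraries labelled left and 6.65 ± 3.67 in those labelled right, and hsa-mir-217 64.6 ± 52.5 and 18.0 ± 12.4 (SD, n = 4 each). The values of hsa-mir-216a did not overlap, at 12.2 to 84.4 CPM in the libraries labelled left and 2.11 to 11.07 CPM in those labelled right. Its choice by a small p favours such a gap, and the share of all miRNAs with 1 was not counted. The miRNA that was lower by DESeq2, hsa-mir-941-3, stood at -2.14 ± 0.50 (SE) and belongs to a family of near-identical copies, so its count is uncertain. All 3 went 1 way in 4 of 4 labelled pairs, which a test with patient as a block favours, and were named after their values were seen.

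Blood cell miRNAs lay higher and neuronal miRNAs lower, as groups, in the libraries labelled left by camera with the preset correlation, and neither call held with an estimated correlation or with fry. Of 16 blood cell miRNAs 15 were positive (median log2 fold change 0.31; camera adjusted p = 0.000327, against an adjusted p of 0.646 with an estimated correlation), among them the red cell miRNAs hsa-mir-144 at 1.94 ± 0.73 (SE) and hsa-mir-451 at 1.42 ± 0.59, and hsa-mir-182 at 1.27 ± 0.48. hsa-mir-451 averaged 2709 ± 679 CPM in the libraries labelled left and 1361 ± 1103 CPM in those labelled right (SD, n = 4 each). It was low in the libraries labelled right of patients 2 and 3, at 616 and 260 CPM, whose mRNA libraries also had the least HBB, while the other 2 labelled right, at 2581 and 1990 CPM, lay within the 1907 to 3391 CPM of those labelled left. The 10 neuronal miRNA names took in 18 tested hairpin rows, so copies of 1 miRNA can count more than once. Of these rows 15 were negative, led by hsa-mir-9-2 at -1.43 ± 0.40 (SE). Their median was -0.26, with a camera adjusted p of 0.0249, against an adjusted p of 0.646 with an estimated correlation. In both lists 0 members passed edgeR's threshold, over all miRNAs or adjusted over the list alone. Without the patient block 1 list stayed called, with neurons at a camera adjusted p of 0.0587. Neurons also stood at 0.535, 0.0621 and 0.102 without patient 1, 2 or 3, and blood cells at 0.114 without patient 3. Over the left-out patients hsa-mir-451 ran from 0.76 to 1.96 and hsa-mir-182 from 0.84 to 1.73.

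The other miRNA lists were not called. Heart muscle miRNAs had a median of -0.14 (camera adjusted p = 0.360), with hsa-mir-499, which lies within a myosin gene, at -0.32 ± 0.21 (SE) and lower in 4 of 4 labelled pairs. Smooth muscle and fibroblast miRNAs stood at -0.07 (0.360), with hsa-mir-29b-1 at -0.41 ± 0.22. Endothelial miRNAs had a median of 0.04 (0.849), the let-7 family -0.02 (0.942, with camera in the other direction), the imprinted cluster on chromosome 14 0.10 (0.234) and the miR-17 to miR-92 clusters -0.11 (0.360). With the preset correlation the chromosome 14 cluster was called lower without patient 1 (camera adjusted p = 0.00862) and higher without patient 3 (0.0181) or 4 (0.00102), and the miR-17 to miR-92 clusters were called lower without patient 3 (0.0181). Epithelial and mesothelial miRNAs stood at 0.15 (0.360), with hsa-mir-200b at 0.95 ± 0.45 (SE). Of the miRNAs in HOX clusters 2 were tested, too few for camera, with hsa-mir-10a at -0.20 ± 0.36. Over the left-out patients hsa-mir-499 ran from -0.39 to -0.14, hsa-mir-29b-1 from -0.57 to -0.27, hsa-mir-200b from 0.58 to 1.31 and hsa-mir-10a from -0.49 to 0.20.

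Many miRNAs are cut from the transcript of a host gene, so the fold changes of a miRNA and its host can be set side by side. Pairs were matched by miRNA name, without position or strand, so some miRNAs may not be cut from the gene they are paired with. This holds for hsa-mir-1-1 and hsa-mir-1-2, which were both paired with MIB1. Across 44 host genes 27 had the same sign of log2 fold change as the mean of their miRNAs. The correlation across genes, which are not independent replicates, was r = 0.587 (permutation p = 9.0e-05, adjusted p = 0.00018) and rho = 0.349 (permutation p = 0.0207, adjusted p = 0.0207), with 2 coefficients in the family. It rested on the 2 hosts whose miRNAs lay farthest from the median. These were the imprinted gene MEST, at 0.74 with hsa-mir-335 at 1.12, and SLIT3, a guidance ligand, at 1.12 with hsa-mir-585 at 1.10. Without them r was 0.296 (permutation p = 0.0567), and without patient 3 it was 0.266, while rho was 0.178 without patient 1 and 0.204 without patient 2. MYH7 stood at 0.23 with hsa-mir-208b at 0.56, and MYH6 at -0.14 with hsa-mir-208a at -0.28.

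**Figure D4:**
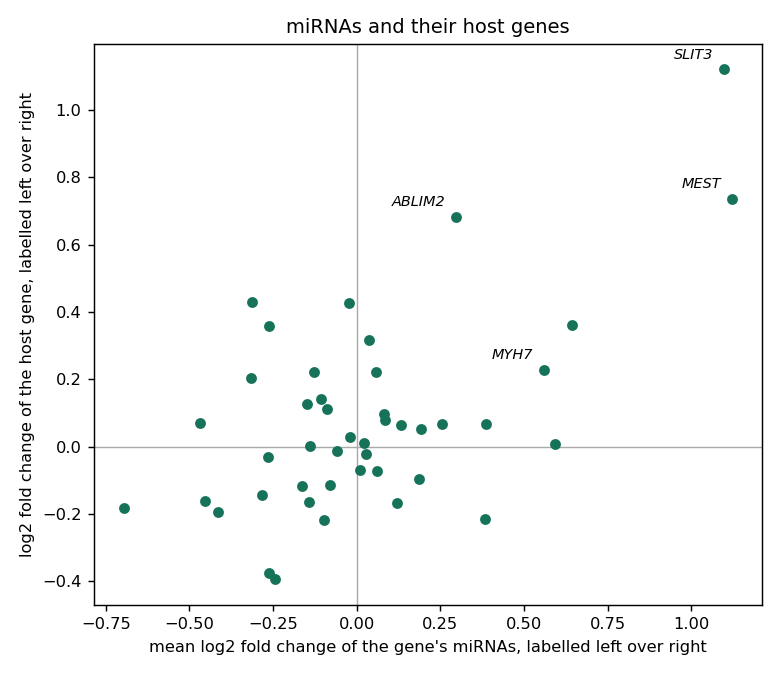
Log2 fold change of each of 44 host genes (vertical axis) against the mean log2 fold change of the miRNAs paired with it by name (horizontal axis), both labelled left over labelled right. MEST and SLIT3 lie at the top right, at 1.12 and 1.10 on the horizontal axis, apart from the other hosts.

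Patient number and side label took close to, or less than, the share of variance that their degrees of freedom alone give. Patient took 45.3% of the sum of squares of log2 CPM over the tested mRNAs and 43.4% over the tested miRNAs, where its degrees of freedom alone give 42.9%. Side took 10.8% and 14.1%, where its degree of freedom gives 14.3%. Of the 8 mRNA libraries 1 correlated best with its labelled partner, and of the 8 miRNA libraries 0 did. The mRNA libraries labelled left of patients 1 and 2 were each other's best match at r = 0.957, across genes, and so were the miRNA libraries with those labels at r = 0.986.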

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

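Single libraries that stood apart from the other 3 of their labelled group were looked for among the named genes and miRNAs and the library totals. HAMP and hsa-mir-24-2, both outside the rule, were added to these. Of 112 groups of 4 values 10 had such a library, and chance alone gives about 1 in 20, or 5.6. The added hsa-mir-24-2 gave 1 of the 10, so this count is not free of picked rows. All tests of explanations in this part were chosen after the results were seen.

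HEYL, a Notch target, stood at 76.2 CPM in the mRNA library labelled left of patient 2, against 52.3 to 55.0 in the others labelled left. The proteoglycan gene LUM stood at 327.5 CPM in the same library, against 133 to 145. The contractile gene TAGLN stood at 397 CPM in the library labelled left of patient 4, against 215 to 238, and AGTR1 at 10.5 CPM there, against 15.8 to 15.99. The library labelled right of patient 2 had a total of 19567339 counts, against 12900412 to 13653347 in the others labelled right. TEK, an endothelial receptor kinase, stood at 9.88 CPM in the mRNA library labelled right of patient 4, against 33.7 to 39.5. hsa-mir-182 stood at 33.2 CPM in the miRNA library labelled left of patient 4, against 45.3 to 47.6, and hsa-mir-29b-1 at 878 CPM in that labelled right of patient 1, against 1445 to 1566.

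BMP10 and HAMP split the libraries in a way that 4 of the 8 side labels do not follow, those left of patients 2 and 3 and right of patients 3 and 4. IRX3, HCN4 and hsa-mir-100, picked after that split was known, part the libraries in the same way. Labels correct in both side and patient number are argued against, because 2 of the 4 labelled pairs failed a check of donor identity. That check does not tell the side of a library, so correct sides with donors who differ in these genes stay open. Mislabelled libraries stay open and may account for the pattern: by mean correlation the labelled pairing ranked 36 among the 105 ways to pair the 8 mRNA libraries. The pairing with the highest mean correlation was the same in both assays and held 0 labelled pairs. It put 1 of the 4 libraries highest in BMP10 into each pair, as 24 of the 105 pairings do. It also joined the libraries labelled left of patients 1 and 2, the highest in adipocyte genes (mean centred log2 CPM 2.73 and 0.98). Another of its pairs was that labelled right of patients 2 and 3, the lowest in red cell genes (-3.59 and -2.81). Correlation cannot tell a shared donor from a shared content of other cells, so these ranks do not decide about the labels. Whether sides, patient numbers or both are wrong stays open. Labels unrelated between the mRNA and miRNA libraries are argued against, though a few mismatched libraries are not excluded: the mean correlation of miRNA and host gene over 54 pairs was 0.203, reached by 17 of the 40320 ways to match the libraries, the labelled match included (exact permutation p = 0.000422, one-sided), and 0.253 was the highest other.

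SLPI, a protease inhibitor of epithelial surfaces, stood at 74.2 CPM in the mRNA library labelled right of patient 4, against 2.38 to 3.35 in the others labelled right, and other mesothelial genes did the same in both libraries labelled patient 4. For 10 of the 15 tested genes of the mesothelium and epicardium list these were the 2 highest libraries, where chance gives 0.536. A lower share of heart muscle is argued against, since the median log2 difference of this pair from the other 6 libraries was below 0 for 7 of 10 lists of other cell types. It ran from -1.21 for neurons and Schwann cells to 2.47 for red cells, and was 0.26 for the sarcomere list. Mesothelial cells from the surface of the heart are a candidate source that stays open. The most abundant of their genes was ITLN1, at 2098 and 1208 CPM against at most 127.5 elsewhere, though 7 of the 15 genes had a median of 10 CPM or more in the other libraries and 2 are in another list.

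hsa-mir-24-2 and the rows set beside it here are outside the rule. hsa-mir-24-2 stood at 2357 CPM in the miRNA library labelled left of patient 1, against 54351 to 80127 in the others labelled left. Whether mature miR-24 was lower there stays open. hsa-mir-3074, annotated at the locus of the other miR-24 copy, stood at 145% of its median in the other 7 libraries. That row is a separate hairpin and was not shown to measure mature miR-24, so its level cannot decide the question. The ratio of hsa-mir-24-2 to hsa-mir-3074 was 0.0491 in this library and 1.61 to 1.86 in the others. The row of hsa-mir-24-1 had a count of 0 in every library, so only hsa-mir-3074 showed a gain. Reads counted under hsa-mir-3074 do not account for the whole loss, since its gain came to 26.8% of it. Another fault in the counting of hsa-mir-24-2 stays open and was not tested, and no biological explanation was tested.

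Other splits of the 8 libraries decide nothing about the called genes and miRNAs, because the labels gave 0 and every split reaches 0. Without the block that holds for 35 of 35 splits into 4 and 4 in mRNA genes, where the highest other count was 44, and for 35 of 35 in miRNAs, where it was 2. The split with 44 mRNA genes had BMP10 counts of 14 to 62 on 1 side and 1072 to 42376 on the other, which points to a structure of the samples that the labels do not follow. It was picked as the highest of 35, though, and 4 other splits had more mRNA genes at an unadjusted p under 0.05 (1787 to 2720, against 1681), and in miRNAs another split also gave 2. With the block only 8 splits part all 4 pairs, too few for a share under 5%. Among them the highest other count was 2 mRNA genes and 0 miRNAs, each against 0, which all 8 reach. The lists called by camera were 9 for the mRNA labels against 12 at the highest other, with 4 of 8 splits as high, and 2 for the miRNA labels against 5, with 8 of 8 as high.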

How the results depend on the processing

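The counts of genes and miRNAs per direction stayed at 0 in edgeR under other size factors, filters, thresholds, the fit without the patient block, each left-out patient, and without the most abundant features, and were 0 in limma voom, run only with the first settings. Adding repeated symbols or hairpin copies together, chosen after seeing the data, also gave 0. DESeq2 called 1 mRNA gene higher and 3 lower, with 445 genes at an unadjusted p under 0.05, and 2 miRNAs higher and 1 lower, with 24. The cause was not tested. With an estimated correlation, and with fry, 0 mRNA lists and 0 miRNA lists were called, against 9 and 2 with the preset correlation. Without the replicate block 1 miRNA list was called, and the block changed no other count, with 9 mRNA lists and 0 genes or miRNAs without it. Leaving out each patient gave 6 to 9 mRNA lists and 1 to 3 miRNA lists, but not the same ones. Of the mRNA lists only oxidative phosphorylation was called without each of the 4 patients, at a preset camera adjusted p of 0.04997 without patient 3, and of the miRNA lists none was. Macrophages and monocytes were called higher without patient 2 (preset camera adjusted p = 0.000354) and lower without patient 3 (0.00123). Ventricular markers were gained without patient 1 (0.0457), atrial markers without patient 2 (0.0395), and gap junction (0.04997) and immediate early genes (0.00894) without patient 3. Among miRNA lists the chromosome 14 cluster was called lower without patient 1 and higher without patient 3 or 4. The correlation of miRNA and host gene ran from 0.266 to 0.680 over the left-out patients and was 0.296 without MEST and SLIT3, chosen after seeing the data. Total counts in place of TMM factors moved the median log2 fold change of all mRNAs by 0.11, and upper quartile factors moved that of miRNAs by -0.14. Of 720 alternative values of the named genes and miRNAs 706 kept their sign and 0 passed the threshold in edgeR or voom. The 14 with the other sign were 4 of NPPA, 3 of BMP10, 3 of NPPB, 2 of HAMP, 1 of S100A9 and 1 of hsa-mir-10a. BMP10 ran from -1.34 in voom and -0.85 without patient 3 to 2.29 without patient 1, against 0.80. Without 1 of the patients 24 of the 53 named genes and miRNAs turned sign or moved by over 1.5 times on the log2 scale.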

Other observations

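Several genes marked single libraries and not a labelled side, and the genes here were picked after their values were seen. ADIPOQ, the adipocyte hormone adiponectin, stood at 86.6 and 30.7 CPM in the libraries labelled left of patients 1 and 2, against 0.348 to 9.67 in the other 6. LEP, which encodes leptin, stood at 53.2 and 11.4 CPM in the same libraries and at most 1.59 CPM elsewhere, but PLIN4, another fat gene, stood at 519 CPM in the second of them, below 633 and 608 CPM in 2 others. Beta-globin mRNA, HBB, had 3 and 5 counts in the libraries labelled right of patients 2 and 3 and 196 to 410 in the others. The red cell miRNA hsa-mir-144 was low in the small RNA libraries with those same labels, at 14.9 and 16.7 CPM against 134 to 287. Those 2 mRNA libraries were the highest for the neutrophil genes S100A8, at 39.4 and 12.4 CPM, and S100A9, at 69.7 and 23.9 CPM, and for the acute-phase gene SERPINA3, at 368 and 108 CPM. The whole neutrophil list stood at a mean log2 CPM, centred per gene, of 2.12 in the first and -0.19 in the second, where its median of -1.06 was the lowest of the 8.

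Other genes split the libraries as BMP10 did. They were picked after that split was known, and how many genes or miRNAs part the libraries this way by chance was not counted. IRX3, a transcription factor of the conduction system, stood at 14.3 to 22.8 CPM in the libraries labelled right of patients 1 and 2 and labelled left of patients 2 and 3, and at 1.56 to 3.11 CPM in the other 4. HCN4, the pacemaker channel, ran from 20.0 to 54.1 CPM and from 1.88 to 10.4 CPM in those same libraries. Among miRNAs hsa-mir-100 ran from 15434 to 29989 CPM in the libraries with the first set of labels and from 6831 to 8889 CPM in the rest.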
